A study of Mus musculus with 7 samples.

How the data were processed

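Poly(A) RNA was sequenced from pooled choroid plexus of the lateral ventricles of CD-1 mouse embryos, treated with washed red blood cells (3 libraries) or with saline (4 libraries), with directional library preparation per the labels' protocols. The deposited table holds raw read counts per gene for the 7 libraries, with gene positions and exon lengths in the column layout of featureCounts, per the file headers. The submitters' processing notes name cutadapt 2.5, STAR 2.6.1b, featureCounts 2.0.6 and the build GRCm39. The annotation release and the strand and multi-mapping settings of the counting are not given in the sources used here. Values of antisense or overlapping genes, and of near-identical genes such as Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, Hspa1a and Hspa1b, or Ifit3 and Ifit3b, are therefore uncertain, and so are H2-D1 and H2-K1, whose sequences vary between mouse stocks. COX3 of the mitochondrial genome held 6 counts over the red blood cell libraries and 6 over the saline libraries, where COX1 had a mean count of 18887 per library.

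The table lists 40879 genes. The lines of 6 genes (Dst, Neb, Ttn, Syne1, Mycbp2 and Huwe1) are broken over 2 lines each, and these genes were left out. The 6 continuation lines carry no gene name and hold 0.0751% of all counts. Of the 40873 genes analysed, 14808 had 0 counts in every library. Gene types came from a name table matched by symbol, which gave a type for 92.16% of genes, and no coordinates were taken from it. Positions are those of the deposited table on GRCm39.

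Total counts per library ran from 4393860 to 8386928. A count of 3 corresponds to 0.683 CPM (counts scaled to library size) in the shallowest library, saline 4, and to 0.358 CPM in the deepest, saline 3. The common biological coefficient of variation was 13.7%. Chi-square statistics of the counts of each pair of libraries, over genes with at least 20 counts in the pair, lay between 3.6 and 14.19 per degree of freedom, so no pair agreed within sampling noise.

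Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 (robust, two-sided) under R 4.3.3, with TMM normalization and genes kept by filterByExpr, which left 14869 genes. No block was used in the main test. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Log2 fold changes are red blood cells minus saline, with standard errors derived from the F statistic. CPM values of single genes use TMM library sizes. The CPM of a count of 3, summed CPM, and the hepatocyte genes compared over libraries use total counts. List members called over all genes were also counted with DESeq2 and with limma-voom, and the count with sample weights is given where it differs from that of limma-voom. Each of 28 gene lists was tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset inter-gene correlation 0.01), adjusted over the 27 lists with members tested. Members were also counted after adjustment over the list alone. A list score is the mean over members of log2 CPM minus the saline mean of the gene. All 561 list entries matched the table, 13 of them through mitochondrial symbols without a prefix.

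The design, the alternatives, the lists and the rule for named genes were fixed before the data were examined. The rule takes up to 12 genes per direction with the largest log2 fold change among genes past the threshold that have a mean count of at least 50, a symbol that is not a predicted one, and all libraries of one group on the same side of the other. It adds up to 4 members per list past the threshold, or the 2 most abundant members where none passes, and always Hmox1, Slc40a1, Tfrc, Fth1, Slc12a2, Ttr, Otx2, Foxj1, Hba-a1, Hbb-bs, Hbb-y, Alas2, Csf1r, Ccl2 and Il1b. Marco, Relb and further list members that the text names were chosen after their values were seen. Values of some genes that the rule or the lists take are not reported here.

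Alternatives were DESeq2 1.42.0, limma-voom with and without sample weights, other normalizations, other count filters, protein-coding genes alone, a fit without robust estimation, stricter thresholds, a block by replicate number, camera with an estimated correlation, fry, and each library left out in turn. After seeing the data, a fit without red blood cells 2 and saline 4 and a fit with a term for Y-linked transcripts were added. The tests were tried on simulated counts with the means, dispersions and library sizes of this comparison, with 14869 genes, 200 of them changed. The changed genes were drawn from those with a mean count of at least 50, and genes were simulated independently of each other. The rates therefore do not cover genes with fewer counts. Real genes with large changes could also fall short, as Icam1 did at 12.2-fold (edgeR adjusted p = 0.176). edgeR recovered 56.7% of genes changed 1.5-fold, 88.1% of those changed 2-fold and 100% of those changed 4-fold, with 17 calls among unchanged genes out of 180 calls. Figures were drawn with matplotlib 3.10.9.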

Results

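The choroid plexus secretes cerebrospinal fluid and separates it from the blood. Its transcriptome was measured by RNA sequencing in CD-1 embryos, an outbred mouse stock, to ask how red blood cells alter gene expression in this tissue. Lateral ventricle choroid plexus was pooled at E15.5 (embryonic day), 24 h after treatment with red blood cells (3 libraries) or saline (4 libraries). The red blood cells came from washed blood of a donor litter at E14.5. All libraries belong to batch 1. The number of embryos and litters behind each pool is not given in the sources used here, and p-values measure the spread between these libraries. Total counts were 7944404, 6752523 and 5479812 in red blood cells libraries 1 to 3, and 6732139, 6219528, 8386928 and 4393860 in saline libraries 1 to 4.

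Adgre1, Nfkb2, Relb, Marco, Synpo and Ntrk2 were higher after red blood cells, and Ntn1, Sema3f and Tgfa were lower. Lists of interferon, NF-kB and macrophage genes passed camera as higher, but not with an estimated correlation (adjusted p = 0.294, 0.294 and 0.215 with an estimated correlation), and 1 of their members, Adgre1, passed over all genes in edgeR. Ntn1, which encodes the guidance cue netrin-1, fell to 0.522-fold, from 78.9 ± 6.17 CPM (SD, n = 4) to 41.1 ± 1.44 CPM (SD, n = 3). Its log2 fold change was -0.94 ± 0.09 (SE) with an edgeR adjusted p of 0.00265. Adgre1, which encodes the macrophage surface protein F4/80, rose 2.13-fold, from 12.7 ± 1.44 to 26.96 ± 4.59 CPM (SD, n = 4 and n = 3, edgeR adjusted p = 0.0280). Nfkb2, a subunit of NF-kB, rose 2.55-fold, from 11.1 ± 1.58 to 28.2 ± 8.03 CPM (edgeR adjusted p = 0.0306).

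In all, 9 of 14869 genes passed the edgeR test, 6 higher and 3 lower, where 1418 genes had an unadjusted p under 0.05 (776 higher and 642 lower). Synpo, which encodes the actin-associated protein synaptopodin, rose 1.70-fold from 31.7 ± 1.89 to 54.0 ± 7.08 CPM. Ntrk2, the receptor of brain-derived neurotrophic factor, rose 1.40-fold from 585 ± 13.2 to 820.5 ± 69.8 CPM. Tgfa, a ligand of the epidermal growth factor receptor, fell to 0.544-fold, from 32.9 ± 2.38 to 18.0 ± 2.45 CPM. Sema3f, a repulsive guidance cue, fell to 0.700-fold, from 203 ± 9.30 to 142 ± 9.73 CPM. These 4 genes had edgeR adjusted p = 0.0280. Marco, a scavenger receptor of macrophages, and Relb, the NF-kB partner of Nfkb2, also passed but lay below the mean count of 50 set for named genes and were chosen after their values were seen. Marco had 21, 35 and 20 counts with red blood cells and 3, 2, 1 and 1 with saline (edgeR adjusted p = 0.0280), and Relb rose 3.39-fold (edgeR adjusted p = 0.0460). Every red blood cell library lay on the same side of every saline library for 9.59% of genes tested, where chance gives 5.71%.

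On GRCm39, Ntn1 spans 68100190 to 68277652 of chromosome 11 (minus strand), Adgre1 57665581 to 57790529 of chromosome 17 (plus strand) and Nfkb2 46285478 to 46300839 of chromosome 19 (plus strand). Synpo spans 60727053 to 60793241 of chromosome 18 (minus strand), Ntrk2 58954286 to 59281784 of chromosome 13 (plus strand), Tgfa 86172020 to 86252726 of chromosome 6 (plus strand) and Sema3f 107558698 to 107587674 of chromosome 9 (minus strand). Marco spans 120402267 to 120432753 of chromosome 1 and Relb 19340142 to 19363352 of chromosome 7, both on the minus strand. All 9 are protein-coding genes.

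The number of genes past the edgeR threshold moved with single libraries. It was 17, 34 and 283 without red blood cells 1, 2 and 3, 1 without each of saline 1, 2 and 3, and 5 without saline 4, and DESeq2 called 280 genes with the 9 among them. limma-voom called 9 genes, 6 of them shared with edgeR. Ntn1 passed in all 7 fits that left out a library, Adgre1 in 4, Marco, Synpo and Nfkb2 in 3, Tgfa, Sema3f and Ntrk2 in 2, and Relb in 1.

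**Figure D1:**
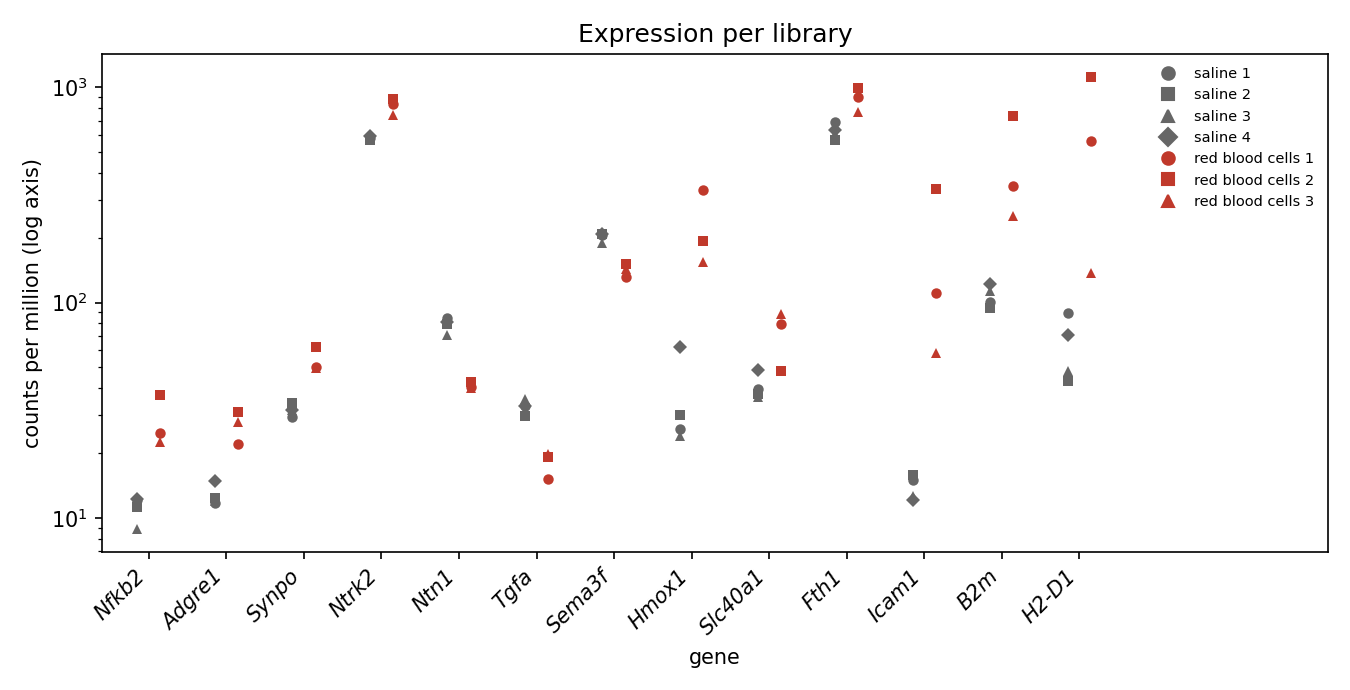
CPM (log axis) of 13 named genes in each of the 7 libraries, with saline in grey and red blood cells in red, and marker shape for the replicate number. Ntn1 lies between 40.2 and 42.8 CPM in the red blood cell libraries and between 70.3 and 85.0 CPM in the saline libraries, while Icam1, B2m and H2-D1 are highest in red blood cells 2.

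Of the 15 fixed lists that passed camera, 0 passed with an estimated correlation (lowest adjusted p = 0.21). Among the 15 the interferon response list had the highest median log2 fold change. All 32 members, from antiviral effectors such as Ifit1 and Oasl2 to antigen presentation genes, were higher with red blood cells, with a median log2 fold change of 2.38. B2m, the light chain of class I antigen presentation molecules, had 446 ± 258 CPM with red blood cells and 108 ± 12.2 CPM with saline (log2 fold change 2.05 ± 0.40, SE). H2-D1, a class I heavy chain, had 607 ± 493 and 62.8 ± 21.3 CPM (SD, n = 3 and n = 4). The 32 members rose when adjusted over the list alone, and 0 passed over all genes in edgeR. Over all genes 32 had an unadjusted p under 0.05, DESeq2 called 30 and limma-voom called 1, or 5 with sample weights. The list passed camera (adjusted p = 4.43e-31), but not with an estimated correlation (adjusted p = 0.294 with an estimated correlation). Its score was 2.203, 3.65 and 1.15 in red blood cells 1, 2 and 3, and between -0.38 and 0.47 in the saline libraries, saline 4 being the highest. Without red blood cells 2 the median was 1.54.

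Inflammatory cytokine and NF-kB genes followed the same direction, with 13 of 13 tested members higher and a median log2 fold change of 1.19. Icam1, an adhesion molecule for leukocytes, had 169 ± 149 CPM with red blood cells and 13.8 ± 1.79 CPM with saline (SD, n = 3 and n = 4). Vcam1, another leukocyte adhesion molecule, had 718 ± 121 and 507 ± 28.5 CPM. When adjusted over the list alone 9 members passed, Icam1, Vcam1, Tnfaip3, Nfkbia and Socs3 among them, and 0 passed over all genes in edgeR (9 at an unadjusted p under 0.05). Of the 13, DESeq2 called 7 and limma-voom 0, or 2 with sample weights, and DESeq2 also called 4 members below the count filter (Ccl2, Ccl5, Ccl12 and Cxcl10). The score was 1.08, 2.215 and 0.45 in red blood cells 1, 2 and 3, and at most 0.20 with saline. The median was 0.553 without red blood cells 2, 0.594 without red blood cells 2 and saline 4, and 1.985 without the count filter. The list passed camera (adjusted p = 4.13e-10), with adjusted p = 0.294 with an estimated correlation. Ccl2 and Il1b fell below the count filter. Ccl2, a monocyte chemoattractant, had 23, 173 and 7 counts with red blood cells and 5, 4, 5 and 3 with saline, and Il1b had 0, 13 and 1 counts and 1, 0, 0 and 0.

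Macrophage markers were higher for 24 of 25 genes, with a median log2 fold change of 0.87. When adjusted over the list alone 16 rose, among them Adgre1, C1qb and Spi1, and 1 (Adgre1) rose over all genes in edgeR (18 at an unadjusted p under 0.05). DESeq2 called 13 and limma-voom 0, or 2 with sample weights, and the adjusted p of Adgre1 ran from 3.17e-05 to 0.172 over the alternatives. The score was 0.59, 1.19 and 0.80 in red blood cells 1, 2 and 3, and at most 0.15 with saline. Csf1r, the receptor that macrophages depend on, had 94.9 ± 19.3 CPM with red blood cells and 64.3 ± 6.54 CPM with saline (log2 fold change 0.56 ± 0.14, SE, edgeR adjusted p = 0.163 over all genes). The list passed camera (adjusted p = 1.2e-18), with adjusted p = 0.215 with an estimated correlation. Complement genes were higher for 12 of 14 members (median 0.55, camera adjusted p = 2.56e-05), with adjusted p = 0.294 with an estimated correlation. Of these 4 members (C3ar1, C5ar1 and C4b among them) rose when adjusted over the list alone, against 0 over all genes in edgeR (6 at an unadjusted p under 0.05, 4 by DESeq2, 0 by limma-voom, or 1 with sample weights). The median was 0.276 without red blood cells 2, 1.23 without saline 4, 1.08 without both, and 0.997 with limma-voom. C3 itself had 304 CPM in red blood cells 2 and 409.5 CPM in saline 4, against 0.718 to 19.01 CPM in the other libraries, and Clu had a log2 fold change of 0.05 ± 0.08. Of 17 neutrophil and monocyte markers 6 could be tested, and all 6 were higher (median 1.99, camera adjusted p = 0.0414, and adjusted p = 0.508 with an estimated correlation). Over the list alone or over all genes 0 passed in edgeR (1 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom). Markers below the count filter went both ways. Summed over red blood cell and saline libraries, Ltf had 17 and 65 counts and Ngp 15 and 28, while Retnlg had 27 and 1 and Mmp8 34 and 1. Single libraries held most of the higher sums. Saline 4 had 41 counts of Ltf and saline 1 had 19 of Ngp, and red blood cells 2 had 26 of Retnlg and 31 of Mmp8. S100a9, a neutrophil calcium-binding protein, had 44.5 CPM in red blood cells 2 and between 0.802 and 5.32 CPM in the other libraries. Prtn3 had a log2 fold change of 0.09 ± 0.24. Without red blood cells 2 the median of this list was -0.075 (adjusted p = 0.419). Its camera call was also lost without red blood cells 3 (0.195), saline 1 (0.0675), saline 2 (0.128), saline 3 (0.162) or saline 4 (0.0630), and its adjusted p ran from 0.00408 to 0.508 over the alternatives. Its median was 1.18 with limma-voom, 0.483 without the count filter and 0.302 without red blood cells 2 and saline 4.

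Heme and iron handling genes were higher for 16 of 22 members, with a median log2 fold change of 0.16. Hmox1, the enzyme that degrades heme, had 227 ± 93.4 CPM with red blood cells and 35.6 ± 18.0 CPM with saline (SD, n = 3 and n = 4), a log2 fold change of 2.72 ± 0.45 (SE, edgeR adjusted p = 0.138 over all genes). The ferritin subunit genes Fth1 and Ftl1 had log2 fold changes of 0.51 ± 0.09 (edgeR adjusted p = 0.0809) and 0.35 ± 0.09 (edgeR adjusted p = 0.157), and the iron exporter gene Slc40a1 0.84 ± 0.21 (edgeR adjusted p = 0.194). When adjusted over the list alone 6 rose (Fth1, Slc48a1, Hmox1, Ftl1, Slc40a1 and Flvcr1) and 1 fell (Lrp1, -0.24 ± 0.07), against 0 over all genes in edgeR (8 at an unadjusted p under 0.05, 6 by DESeq2, 1 by limma-voom, or 2 with sample weights). The transferrin receptor gene Tfrc had 0.34 ± 0.26. The list passed camera (adjusted p = 0.00114), with adjusted p = 0.21 with an estimated correlation. Its median was 0.30 without red blood cells 1, 0.037 without red blood cells 3 and 0.246 without saline 4.

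Lists of stress, cell cycle and lysosome genes also passed camera as higher. Nrf2 antioxidant genes were higher for 17 of 19 members (median 0.29, camera adjusted p = 4.55e-06, and adjusted p = 0.294 with an estimated correlation). Of these 9 rose when adjusted over the list alone, against 0 over all genes in edgeR (11 at an unadjusted p under 0.05, 4 by DESeq2, 0 by limma-voom, or 1 with sample weights). Among the 9 were the glutathione synthesis genes Gclc and Gclm and the cystine transporter gene Slc7a11 (log2 fold change 0.32 ± 0.10), while Tkt had 0.05 ± 0.06. Immediate early and heat shock genes were higher for 17 of 18 members (median 0.325, camera adjusted p = 1.1e-05, and adjusted p = 0.21 with an estimated correlation). Of these 3 (Hspa1a, Btg2 and Atf3) passed when adjusted over the list alone and 0 over all genes in edgeR (4 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom). Klf6 had 0.20 ± 0.12 and Ccn1 0.19 ± 0.25. Unfolded protein and integrated stress response genes were higher for 17 of 21 members (median 0.12, camera adjusted p = 0.0018, and adjusted p = 0.294 with an estimated correlation). Of these 1 (Edem1) passed when adjusted over the list alone and 0 over all genes in edgeR (2 at an unadjusted p under 0.05, 0 by DESeq2 or limma-voom). Hspa5 had 0.12 ± 0.08 and Hsp90b1 0.10 ± 0.08, and the median was 0.069 without red blood cells 2 and 0.068 without saline 1. Cell cycle genes were higher for 21 of 23 members (median 0.14, camera adjusted p = 0.00125, and adjusted p = 0.551 with an estimated correlation). Over the list alone or over all genes 0 passed in edgeR (1 at an unadjusted p under 0.05, 0 by DESeq2 or limma-voom). Mki67 had 0.12 ± 0.13 and Top2a 0.08 ± 0.13, and the call was lost without red blood cells 3 (adjusted p = 0.188; 1.81e-06 to 0.551 over the alternatives). The median was 0.237 without red blood cells 2 and saline 4. Lysosome and phagocytosis genes were higher for 19 of 24 members (median 0.06, camera adjusted p = 0.0213, and adjusted p = 0.551 with an estimated correlation). Of these the scavenger receptor genes Cd36 and Msr1 and Lamp2 made up the 3 past the threshold when adjusted over the list alone, against 0 over all genes in edgeR (3 at an unadjusted p under 0.05, 2 by DESeq2, 0 by limma-voom). Ctsd had -0.07 ± 0.07 and Psap -0.02 ± 0.07. That call was lost without red blood cells 2 (adjusted p = 0.307), saline 2 (0.128) or saline 3 (0.0856), with 0.00127 to 0.551 over the alternatives. Its median was 0.018 without red blood cells 2, 0.111 without red blood cells 3 and 0.104 without saline 4.

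Genes of the choroid plexus epithelium were slightly lower, with 22 of 27 members lower and a median log2 fold change of -0.12. The bicarbonate transporter gene Slc4a5 (-0.39 ± 0.07), the water channel gene Aqp1 (-0.24 ± 0.06) and the sulfate transporter gene Slc13a4 (-0.39 ± 0.11) fell when adjusted over the list alone, 3 in all, against 0 over all genes in edgeR (8 at an unadjusted p under 0.05, 2 by DESeq2, 0 by limma-voom, or 1 with sample weights). Ttr, the most abundant marker, had 11315 ± 1034 CPM with red blood cells and 12055 ± 2031 CPM with saline. Saline 4 had 14879 CPM of Ttr and the other saline libraries 10050 to 11802 CPM. The log2 fold change of Ttr ran from -0.163 to 0.033 over the alternatives. Otx2 (-0.07 ± 0.06) and Clic6 (-0.07 ± 0.07) differed by little more than their errors. The list passed camera (adjusted p = 0.000119), with adjusted p = 0.355 with an estimated correlation, and not without red blood cells 3 (adjusted p = 0.0708; 1.66e-06 to 0.355 over the alternatives), where the median was -0.062. Fluid and ion transport genes were lower for 18 of 27 members (median -0.08, camera adjusted p = 0.0131, and adjusted p = 0.294 with an estimated correlation). When adjusted over the list alone 5 fell (Slc4a5, Trpv4, Aqp1, Fxyd1 and Car2) and 1 rose (Slc12a7), against 0 over all genes in edgeR (7 at an unadjusted p under 0.05, 5 by DESeq2, 0 by limma-voom, or 1 with sample weights). The cotransporter gene Slc12a2 had 0.07 ± 0.17, Car12 0.04 ± 0.07 and Kcne2 -0.07 ± 0.06. This call was lost without red blood cells 3 (adjusted p = 0.102; 0.00116 to 0.294 over the alternatives), and the median was -0.049 without red blood cells 2. Tight junction genes (median -0.12, camera adjusted p = 0.242, with Cldn1 at -0.17 ± 0.07 and Cgnl1 at -0.14 ± 0.07) and motile cilia genes (median 0.00, camera adjusted p = 0.88, direction lower, with Foxj1 at 0.00 ± 0.08 and Cfap44 at -0.13 ± 0.08) did not pass. Adjusted over the list alone, 0 tight junction genes and 1 motile cilia gene (Hydin, lower) passed, against 0 over all genes in edgeR (1 and 4 at an unadjusted p under 0.05, 0 and 1 by DESeq2, 0 by limma-voom).

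**Figure D2:**
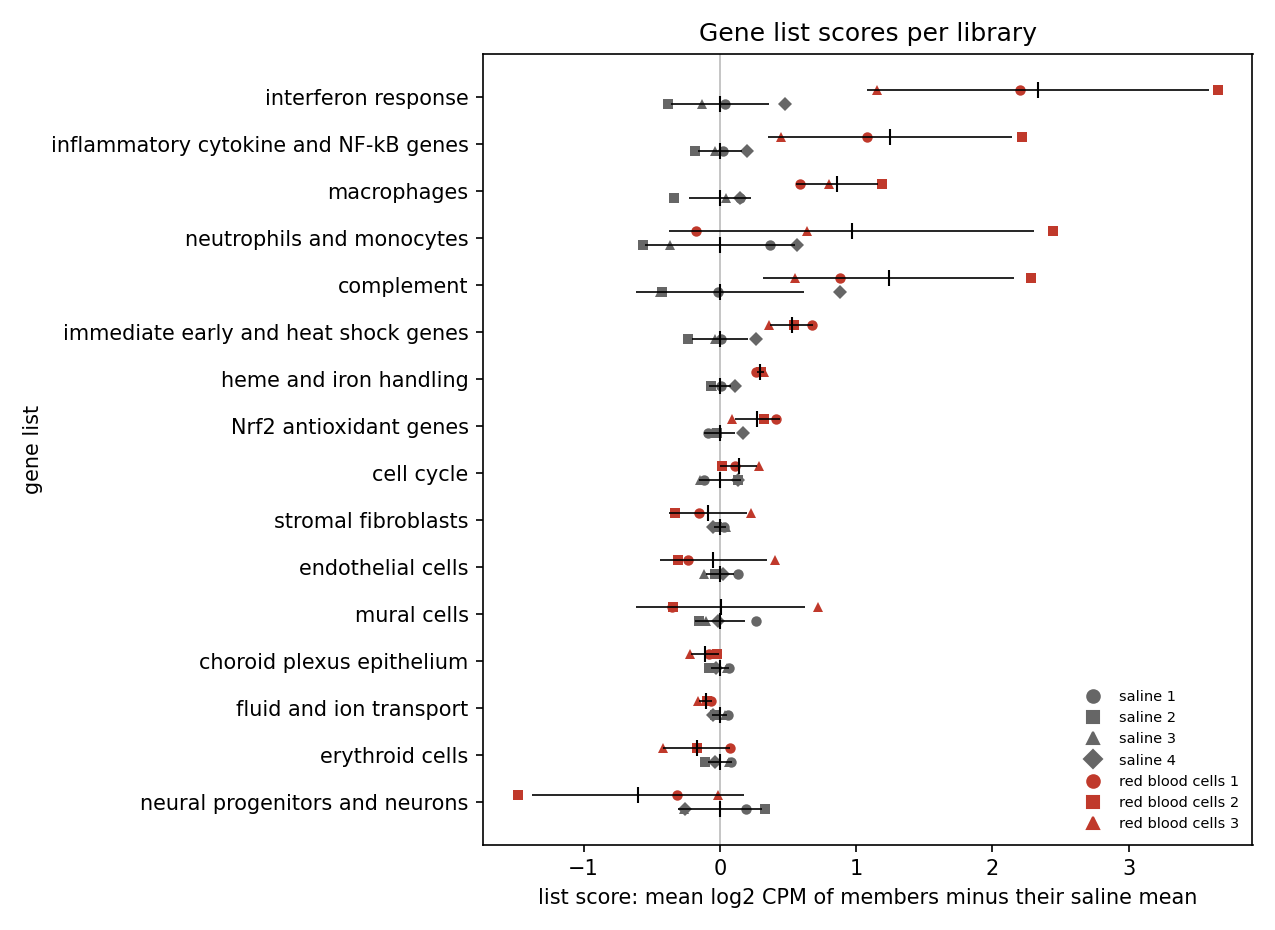
Scores of 16 gene lists per library on a log2 scale, where 0 is the saline mean, with saline in grey, red blood cells in red, marker shape for the replicate number, and black ticks and lines for mean and SD (n = 4 and n = 3). Interferon response scores are 2.203, 3.65 and 1.15 with red blood cells, and scores of neural progenitors and neurons are lowest, at -1.48, in red blood cells 2.

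Erythroid genes were lower for 14 of 17 members (median log2 fold change -0.225, camera adjusted p = 0.0251), with adjusted p = 0.551 with an estimated correlation. Of these 1 (Sptb) fell when adjusted over the list alone, against 0 over all genes in edgeR (3 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom). The adult globin genes Hba-a1 and Hbb-bs had log2 fold changes of -0.05 ± 0.14 and -0.01 ± 0.11, and Alas2, the erythroid heme synthesis enzyme, -0.23 ± 0.36. The embryonic globin genes Hbb-y and Hba-x had higher values, 0.72 ± 1.08 (edgeR adjusted p = 0.922) and 0.52 ± 0.71 (edgeR adjusted p = 0.909), Hba-x being chosen after its values were seen. The value of Hbb-y ran from 0.316 to 1.796 over the alternatives and passed in none of them. The call was lost without red blood cells 3 (adjusted p = 0.132), saline 1 (0.11) or saline 3 (0.0928), with 0.000701 to 0.551 over the alternatives. The median was -0.14 without red blood cells 3 and -0.093, -0.338, -0.13 and -0.392 without saline 1, 2, 3 and 4, and -0.412 without red blood cells 2 and saline 4. Markers of neural progenitors and neurons were lower for 14 of 17 members (median -0.59, camera adjusted p = 0.00201, and adjusted p = 0.551 with an estimated correlation). Over the list alone or over all genes 0 passed in edgeR (1 at an unadjusted p under 0.05, 0 by DESeq2 or limma-voom). Sox11 had -0.36 ± 0.29 and Sox2 0.15 ± 0.08. The score was -1.48 in red blood cells 2, and without that library the call was lost (adjusted p = 0.513; 1.11e-06 to 0.551 over the alternatives). The median was -0.286 without red blood cells 2, -0.987 without red blood cells 3, -0.299 without saline 2, -0.364 without red blood cells 2 and saline 4, and -0.315 with at least 10 counts in every library.

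The other lists did not pass camera. Stromal fibroblast genes had a median of 0.08 and a mean of -0.04 (adjusted p = 0.187, direction lower), with Ogn at -0.02 ± 0.08. Of these 2 (Postn and Fbn1) fell when adjusted over the list alone, against 0 over all genes in edgeR (3 at an unadjusted p under 0.05, 2 by DESeq2, 0 by limma-voom). Endothelial genes had a median of 0.01 (adjusted p = 0.33, direction lower), with Cdh5 at 0.08 ± 0.17 and Kdr at -0.10 ± 0.09. Mural cell genes had a median of 0.07 (adjusted p = 0.776), with Pdgfrb at 0.08 ± 0.12 and Rgs5 at -0.01 ± 0.19. Cortical hem genes had a median of 0.11 (adjusted p = 0.733, direction lower), with Rspo2 at 0.23 ± 0.16 and Bmp7 at -0.18 ± 0.10. Scores of stromal, endothelial, mural and cortical hem genes were highest in red blood cells 3 (0.23, 0.40, 0.72 and 0.56). Without that library all 4 lists passed camera as lower, stromal at a median of -0.253 (adjusted p = 5.65e-05), endothelial at -0.251 (1.15e-05), mural at -0.293 (0.0191) and cortical hem at -0.322 (0.0323). Platelet genes (median 0.16, adjusted p = 0.751, Itga2b at -0.05 ± 0.13 and Itgb3 at 0.09 ± 0.20), hypoxia and glycolysis genes (median -0.03, mean 0.00, adjusted p = 0.654, direction lower, Eno1 at 0.06 ± 0.10 and Pgk1 at -0.05 ± 0.08) and cholesterol synthesis genes (median 0.045, mean -0.04, adjusted p = 0.751, direction higher, Hmgcs1 at 0.09 ± 0.26) had 0 members past the threshold over the list alone or over all genes in edgeR (0, 1 and 0 at an unadjusted p under 0.05), and 0 by DESeq2 or limma-voom. In endothelial, mural, cortical hem, mitochondrial and hepatocyte lists edgeR, DESeq2 and limma-voom called 0 members over all genes, and edgeR 0 adjusted over the list alone. In edgeR 1 cortical hem gene and 0 genes of the other 4 lists had an unadjusted p under 0.05. TGF-beta and matrix remodelling genes had a median of 0.02 (adjusted p = 0.824, direction lower). Of these 1 member (Mmp9, higher) passed when adjusted over the list alone and 0 over all genes in edgeR (4 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom). Col4a1 had 0.13 ± 0.14 and Sparc -0.17 ± 0.08. Mitochondrially encoded genes had a median of -0.01 (adjusted p = 0.776), with COX1 at 0.01 ± 0.15 and CYTB at -0.05 ± 0.12. Of 12 hepatocyte genes 3 could be tested (median -4.82, adjusted p = 0.553, and 0.0118 without the count filter), and Afp had 804 CPM in saline 4 and at most 14.2 CPM in the other libraries. Of 14 lymphocyte genes 0 passed the count filter.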

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

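The tests of the hepatocyte and mislabelling explanations were chosen after the results were seen. In the saline group, 99 values (named genes, list scores and library measures) were examined for a library far from the other 3, and 6 stood out, where chance gives about 5. Of these, 5 concerned saline 4 and 1 saline 3.

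Afp, the fetal serum protein alpha-fetoprotein, had 804 CPM in saline 4 and 0 to 14.2 CPM in the other saline libraries. The pattern extended over hepatocyte genes: 11 of 12 list members, fixed before the data were examined, reached at least 10 times their level in any other library, with Afp at 789.7, Alb at 469.5 and Apob at 175 CPM on total counts, while Vtn, which is also on the mural list, did not. A candidate explanation is that hepatocytes or their RNA entered this pool, a hypothesis from the same data, and no sort or gate that would remove them is given in the sources used here. A mislabelled red blood cell library was argued against but not excluded. The interferon score of saline 4 was 0.474, the highest of the saline libraries (SD 0.359), and the lowest red blood cell library had 1.154. The red blood cell scores spread widely (2.336 ± 1.254, SD, n = 3). The complement (0.879) and Nrf2 (0.167) scores of saline 4 lay among those of the red blood cell libraries, while its NF-kB (0.198) and macrophage (0.145) scores lay below them. The complement list includes C3, at 409.5 CPM in saline 4, 0.718 to 7.54 CPM in the other saline libraries and 304 CPM in red blood cells 2. A complement score without C3 was not computed, so this score cannot decide on mislabelling. No biological explanation was tested, and without saline 4 the number of genes changed was 5.

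C3, a complement protein, had 409.5 CPM in saline 4 and 0.718 to 7.54 CPM in the other saline libraries. Hmox1 had 62.3 CPM in saline 4 and 24.0 to 30.0 CPM in the others. Kcne2 had 1444 CPM in saline 4 and 1286 to 1312 CPM in the others. The cholesterol synthesis score was 0.341 in saline 4 and -0.15 to -0.08 in the others. Sema3f had 189 CPM in saline 3 and 206 to 209 CPM in the others.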

How the results depend on the processing

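The fits without red blood cells 2 and saline 4 together and with a term for Y-linked transcripts were chosen after seeing the data, and so were the tests against other splits. The number of genes changed (9, with 6 genes higher with red blood cells and 3 genes lower with red blood cells) was 280 (222 and 58) with DESeq2, 48 (40 and 8) with sample weights in limma-voom, 136 (102 and 34) without the count filter and 40 (31 and 9) without red blood cells 2 and saline 4. It was 16 (13 higher) without robust estimation, 4 (0 lower) with an absolute log2 fold change above 1, and 1 (0 higher, 1 lower) at an adjusted p under 0.01. With each library left out it ran from 1 to 283 (0 to 226 higher, 1 to 57 lower), and lists changed from 12 to 15. The cause was not tested. The replicate block gave 2 genes (2 higher, 0 lower, with 1202 genes at an unadjusted p under 0.05 in edgeR), Oas1a and Cd74, and 15 lists. Deviations of libraries with the same number correlated at -0.01, -0.17 and -0.17 (highest of all pairs 0.261, red blood cells 1 with saline 3). These few values gave no sign of pairing by number but cannot exclude it. The number of lists changed (15) was 0 in camera with an estimated correlation (4 at an unadjusted p under 0.05) and 0 in fry (9 at an unadjusted p under 0.05). The mural list turned from 0.07 to -0.293 without red blood cells 3 (adjusted p = 0.0191; -0.293 to 0.184 with each library left out, and adjusted p 0.0191 to 0.991 over the alternatives). All 9 called genes kept their sign in each alternative that gave them a value, and 110 gene and list values short of the threshold in both fits changed sign. Of the 35 splits of the libraries into 3 and 4, 2 gave as many genes changed as the real 9 (highest other 10, for red blood cells 3 with saline 2 and saline 4), 2 as many lower as 3 (highest other 6) and 5 as many lists as 15 (highest other 17), so chance was not excluded for these. For genes higher the real split alone gave as many (1 of 35 splits, real value 6, highest other 4), the only count of those compared to do so. Chance was not excluded here either, since 1 of 35 is the smallest share possible. The split of red blood cells 3 with saline 2 and saline 4 also gave 6 lower. The neutrophil call was lost without the count filter (0.0622), with at least 10 counts in every library (0.113) and without red blood cells 2 and saline 4 (0.095), which also ended the neural call (0.0661). With the block the median was 1.181 for complement and -0.374 for erythroid genes. A count of 3 stood for 0.683 CPM in the shallowest library, saline 4.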

Other observations

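The tests of explanations in this part, and the fit with a term for Y-linked transcripts, were chosen after the results were seen. Hbb-y, an embryonic globin gene, had 1.33 CPM in saline 1, 4.19 in saline 3 and 11.3 in red blood cells 2, against 31.1 to 38.6 CPM in the other 4 libraries. Hbb-bs, an adult globin gene, stayed between 992 and 1315 CPM. The libraries also differed in Y-linked transcripts (Ddx3y, Eif2s3y, Kdm5d and Uty, named after their values were seen): their sum was 0.38 CPM in red blood cells 1 and 0.48 CPM in saline 3, and 126 to 195 CPM in the other 5, while Xist was present in all 7 (644 to 1677 CPM). With a term for this difference 6 genes passed, 5 of them among the 9.

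Saa3, Cxcl10 and Ccl5 lay below the count filter and were chosen after their values were seen. Saa3, an acute phase gene, had 17, 613 and 6 counts in red blood cells 1, 2 and 3 and 1, 1, 2 and 6 in saline 1 to 4. Cxcl10, an interferon-induced chemokine gene, had 14, 67 and 5 counts with red blood cells and 0, 0, 1 and 1 with saline. Ccl5 had 10, 52 and 3 counts, and 0 in each saline library.

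Interferon, NF-kB and macrophage genes were higher in each red blood cell library than in any saline library by list score. An exact two-sided permutation test gave p = 0.0571 for each of these 3 lists, the smallest that 3 against 4 allows. Heme and iron handling and immediate early and heat shock genes separated as fully (exact two-sided permutation test, p = 0.0571). Fluid and ion transport genes did so as lower (exact two-sided permutation test, p = 0.0571), but narrowly. Their highest red blood cell score was -0.065 and their lowest saline score -0.054. In the other lists that passed camera the groups overlapped (exact two-sided permutation test, p = 0.114 to 0.343). Red blood cells 2 alone was argued against: without it the lowest median log2 fold change of the 3 lists was 0.553, for NF-kB genes (highest camera adjusted p of the 3 lists 1.43e-09, where with all libraries adjusted p = 0.294, 0.294 and 0.215 with an estimated correlation and 0.0886, 0.0886 and 0.0841 in fry). Summed CPM did not settle whether erythroid cells left from the donor blood were the whole source of the interferon transcripts. The erythroid sum showed no rise (-144.1 ± 367, SE), but the difference of the interferon sum was itself uncertain (2356 ± 1210, SE). By list score, erythroid genes stood at 0.075, -0.167 and -0.416 in red blood cells 1, 2 and 3. Their saline scores lay between -0.109 and 0.078, so no red blood cell library exceeded the saline range, although 3 of 17 members were higher. These scores argue against such erythroid cells as the whole source, without excluding them. The interferon score exceeded the macrophage score by 1.478 ± 1.061 (SD, n = 3). In red blood cells 1 and 2 the excess was 1.613 and 2.466. There it argued against a larger share of macrophages with the same levels per cell as the whole cause. Red blood cells 3 cannot decide, since its excess was 0.356 and that of saline 4 was 0.329. A response of the tissue to red blood cells may remain, as a hypothesis, beside a part from erythroid cells of the donor blood and a larger share of macrophages in red blood cells 3. Incoming macrophages with other levels per cell, white cells of the donor blood and an agent in the donor preparation also stay open and were not tested.

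Choroid plexus epithelium genes were slightly lower with red blood cells, but by list score the groups overlapped (exact two-sided permutation test, p = 0.286). A lower share of epithelial cells would raise the markers of other cell types alike, and cannot be told apart, since the macrophage score lay 1.041 ± 0.688 (SD, n = 3) above the mean score of endothelial, mural, stromal and neural markers over all 3 libraries but 0.464 in red blood cells 3. That library had the lowest epithelium score (-0.221), and its macrophage (0.798), mural (0.717), endothelial (0.402) and stromal (0.228) scores were above 0, with the neural score at -0.013. In red blood cells 1 and 2 the mural (-0.355 and -0.348), endothelial (-0.237 and -0.307) and stromal (-0.154 and -0.332) scores were below 0. So were their neural scores (-0.312 and -1.48). Their epithelium scores (-0.078 and -0.022) lay within the saline range (-0.081 to 0.063). Dilution of every epithelial gene by the same factor cannot be told apart from unequal change, since 3 of 27 members lay over 2 SE from the list median, where chance gives 1.23. Added macrophages and a response to the treatment stay open. The camera call was lost without red blood cells 3, where the median was -0.062 (adjusted p = 0.0708). With all libraries the list also failed to pass with an estimated correlation (adjusted p = 0.355) and in fry (adjusted p = 0.153). Its adjusted p ran from 1.66e-06 to 0.355 over the alternatives.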
